A study of Homo sapiens with 8 samples.

How the data were processed

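The values analysed are the raw read counts per gene that the authors deposited, in 8 columns, 1 for each library, over 54628 genes, and every library was used. The unit is counts, and no value contradicted it. Per the labels' protocols, RNA was taken by acid phenol extraction with an RNA integrity number above 7.0, libraries were made with the TruSeq Stranded mRNA kit and they were sequenced on a NovaSeq instrument. The submitters' processing notes name Trimmomatic 0.36, HISAT2 2.1.0, featureCounts 1.6.3 and the hg38 build. Their settings, the annotation and the strand option are not given in the sources used here, so the values of a gene that overlaps another or has close paralogs, such as WTAPP1, MMP1, IFIT1, KRT8, KRT18, OR7E19P and ACTG1P20, are uncertain.

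Libraries were placed in groups by the treatment stated in their labels. The labels number the replicates of a group in different ways in the title and in the description, and replicate numbers here follow the title. Neither number pairs libraries across groups by any statement in the labels, and correlations of residuals between libraries with the same title number ran from -0.0121 to 0.159 across genes, so the replicate number was left out of the model and used only as an alternative.

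Counts were analysed with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3, and plots were drawn with matplotlib 3.10.9 in Python 3.11.15. Genes passing filterByExpr on the groups, 17155 of them, were scaled with TMM factors and fitted with edgeR's robust quasi-likelihood model with 4 groups and 4 residual degrees of freedom. The common biological coefficient of variation was 0.0904 and the median prior degrees of freedom 11.2. Each of 5 contrasts was tested two-sided with the quasi-likelihood F test at an adjusted p of 0.05 by Benjamini-Hochberg over the genes tested: bleomycin without doxycycline, bleomycin with it, doxycycline in proliferating cells, doxycycline in senescent cells, and the difference of the last 2. Levels in CPM use the TMM factors, whose group means were 1.03, 1.03, 0.916 and 1.03 in the order proliferating, proliferating with doxycycline, senescent and senescent with doxycycline. Log2 changes are those of the fit and log2 CPM used a prior count of 2. SE is that of the fitted log2 change.

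Where a group had no counts, a bound takes 3 counts over the group, which is 0.0371, 0.0399, 0.0437 and 0.0400 CPM in the same order of groups. Where it had 1 to 3 counts, a ratio of counts with its 95% interval is given. Intervals and floors cover counting error only.

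The design, the alternatives and 27 gene lists with 624 genes were fixed before the data were examined. All 624 list genes were found, 15 of them under another symbol. The lists are YAP/TAZ-TEAD targets, Hippo pathway and TEAD factors, mitotic genes, DNA replication genes, p53 targets, senescence-associated secreted factors, NF-kappaB pathway genes, interferon-stimulated genes, MHC class I presentation, ligands of NK and T cell receptors, smooth-muscle genes, collagens and matrix proteins, focal adhesion and actin genes, TGF-beta response genes, AP-1 and immediate-early genes, ribosome biogenesis genes, lysosomal genes, cholesterol synthesis genes, ATF4 targets and amino acid synthesis, mitochondrially encoded mRNAs, unfolded protein response genes, the BCL2 family, senescence regulators and chromatin genes, and epithelial, endothelial, leukocyte, and neuronal and glial markers. Each list was tested in each contrast with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg over the 27 lists. With a correlation estimated from the data no list passed in any contrast, while 3, 2, 5, 7 and 5 lists had an unadjusted p under 0.05 (doxycycline in proliferating cells, in senescent cells, bleomycin without and with doxycycline, interaction). Limma's fry, which asks whether the genes of a list move one way and does not compare them with other genes, called 19, 22, 22, 20 and 15 lists.

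Genes named are YAP1, the 8 with the largest rise and the 8 with the largest fall per contrast among genes past the threshold with a mean log2 CPM of at least 3 and no overlap between the libraries compared, and up to 4 members per list with the largest change. Loci without a proper symbol were passed over, and for the interaction the overlap was not asked for. Genes of a list may also be named where that list is described.

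The alternatives were DESeq2's size factors in edgeR, total counts only, limma-voom, DESeq2, no filter, a mean log2 CPM of at least 1, only the 4 libraries compared, the title's replicate number as a block, the description's number as a block, a test against a 1.5-fold change (glmTreat), a fit without robust estimation, and each library left out in turn. In a library left out, the lone sample of its group is assumed to vary like the others. Relations between contrasts were computed across genes and set against 20 simulations of unchanged groups.

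The tests were run on simulated counts of the same size, in which 100 genes changed 2-fold and 100 changed 4-fold. Of these edgeR recovered 67 and 89 for doxycycline in proliferating cells, 70 and 89 in senescent cells, 68 and 88 for bleomycin without doxycycline, 60 and 87 with it, and 53 and 76 for the interaction, all in the right direction. Among the 16955 unchanged genes it called 14, 12, 8, 16 and 12. These made up 8.24, 7.02, 4.88, 9.82 and 8.51% of its calls in the same order of contrasts. The share of false calls was thus above the adjusted p threshold in every contrast except bleomycin without doxycycline. Splicing, transcript isoforms and read-level data were not analysed here.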

Results

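Messenger RNA was measured by sequencing in 8 libraries of IMR90-hTERT cells, a human lung fibroblast line kept dividing by telomerase. The cells carried a doxycycline-inducible transgene for YAP5SA with a Flag tag. YAP5SA is a constitutively active form of YAP, the transcriptional coactivator that the Hippo kinases restrain and that acts through the TEAD factors. The libraries form 4 groups with 2 replicates each: proliferating cells and bleomycin-induced senescent cells, each without and with doxycycline. Per the labels, bleomycin, a drug that breaks DNA, was given at 10 ug/ml for 24 hours and senescent cells were assessed 9 days after it. Doxycycline was given at 1 ug/ml for the last 11 days, so in senescent cells it began no later than the bleomycin and lasted while senescence developed. Total counts were 39692162 and 38534702 in the proliferating libraries without doxycycline and 33627708 and 39599531 in those with it. In senescent cells they were 39600145 and 35419680 without doxycycline and 37545738 and 35351961 with it. Levels are given in CPM, the counts of a gene per 1e6 counts of the library, as mean ± SD with n = 2 per group. Gene positions refer to hg38.

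Replicates resembled each other more than they resembled other groups, with Pearson r of log2 CPM across genes from 0.990 to 0.993 within groups and from 0.920 to 0.977 between groups. The first principal component (56.1% of the variance) separated proliferating from senescent libraries, and the second (26.8%) separated libraries without doxycycline from those with it. Mitochondrially encoded mRNAs took 5.76 ± 0.250% of all counts in proliferating cells and 6.96 ± 0.125% when these received doxycycline. The share was 6.26 ± 0.412% in senescent cells and 3.56 ± 0.361% in senescent cells with doxycycline. Replicates differed by more than counting error, with chi-square per degree of freedom of 3.63, 19.5, 15.8 and 12.7 in the groups in the same order. Nothing in the labels says that replicates were separate cultures, so the p-values measure the spread between these samples. The design has no doxycycline-treated cells without the transgene, so the drug and the transgene were compared together.

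YAP1 itself (chromosome 11, 102110447 to 102233424) stood at 197 ± 1.69 CPM in proliferating cells and 214 ± 34.03 CPM with doxycycline (log2 change 0.12, SE 0.10, adjusted p = 0.431). In senescent cells it rose from 207 ± 23.4 to 289 ± 2.83 CPM with doxycycline (log2 change 0.48, SE 0.10, adjusted p = 0.00140). The difference between the states did not pass the test (log2 0.36, adjusted p = 0.101). The count of this gene sums endogenous transcripts and any transgene reads that align to it, so it does not give the level of the transgene alone.

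Bleomycin without doxycycline shows the programme of the senescent state in this line. Mitotic genes fell to a small part of their proliferating level. PLK1, a mitotic kinase (chromosome 16, 23678889 to 23690367), fell from 138 ± 3.61 to 6.71 ± 0.723 CPM (20.5-fold lower, log2 SE 0.10). CDC20, an activator of the anaphase-promoting complex, fell from 181 ± 3.55 to 6.97 ± 1.15 CPM. Interferon-stimulated genes went the other way. OAS2, a sensor of double-stranded RNA (chromosome 12, 112978519 to 113011723), rose from 0.755 ± 0.0664 to 169.7 ± 4.61 CPM (224-fold, log2 SE 0.14). BST2, which tethers budding viruses, rose from 0.831 ± 0.278 to 283 ± 56.6 CPM. The cytokine gene IL1A rose from 0.468 ± 0.201 to 109 ± 34.3 CPM. CDKN1A, the p21 inhibitor of cell cycle kinases (chromosome 6, 36676463 to 36687332), rose 5.003-fold to 1622 ± 128 CPM.

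The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 10155 of 17155 genes, 5108 higher and 5047 lower. Of these 2075 and 1764 changed more than 2-fold in the fit. With total counts as the only scaling the median of all genes moved by -0.17 on the log2 scale. Of the called genes 37.1% were higher, against 50.3% with the TMM factors. Among genes with a mean log2 CPM of at least 3, the largest rises also took in OAS1 (log2 9.27), the interferon-induced MX2 (8.37), the serpin gene SERPINA9 (9.24) and the epithelial transcription factor gene EHF (7.67). CXCR4, a chemokine receptor with no counts in proliferating cells, was at least 27.9-fold higher. Bounds of this kind take 3 counts over the group as the floor and cover counting error only. The largest falls were those of SAPCD2 (log2 -4.81), CDC20 (-4.70), TROAP (-4.70), PIMREG (-4.43), CENPA (-4.40), PLK1 (-4.36), KIF20A (-4.26) and NEK2 (-4.24).

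List counts adjusted over the list alone are given where they differ from those over all genes. All 30 measured mitotic genes fell, and all 30 DNA replication genes fell. The licensing factor gene CDT1 changed by log2 -3.38 and the thymidine kinase gene TK1 by -3.64. The mitotic list had a median log2 change of -3.27 (camera adjusted p = 3.46e-18, and adjusted p = 0.186 with an estimated correlation). The replication list had a median log2 change of -2.52 (camera adjusted p = 9.41e-17, and adjusted p = 0.186 with an estimated correlation). Of 23 senescence regulators and chromatin genes, 4 rose and 18 fell. The senescence regulator list had a median log2 change of -1.23 (camera adjusted p = 9.19e-05, and adjusted p = 0.119 with an estimated correlation). LMNB1, which encodes the lamina protein lamin B and falls in many forms of senescence, went from 126 ± 0.497 to 8.04 ± 1.74 CPM. HMGB2 went from 249 ± 9.93 to 20.9 ± 0.781 CPM and the histone methyltransferase gene EZH2 from 45.4 ± 0.0714 to 6.25 ± 1.91 CPM. Ribosome biogenesis genes were mostly lower, 3 rising and 15 or, adjusted over the list alone, 16 falling of 26. The rRNA methyltransferase FBL changed by log2 -1.55. The ribosome biogenesis list had a median log2 change of -0.36 (camera adjusted p = 0.0126, and adjusted p = 0.279 with an estimated correlation).

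Of 34 interferon-stimulated genes 33 rose and 0 fell. Of 29 senescence-associated secreted factors 27 rose and 1 fell. The interferon list had a median log2 change of 4.31 (camera adjusted p = 3.46e-18, and adjusted p = 0.119 with an estimated correlation). The secreted-factor list had a median log2 change of 3.75 (camera adjusted p = 2.33e-11, and adjusted p = 0.186 with an estimated correlation). The chemokine gene CXCL8 went from 18.2 ± 1.59 to 1027 ± 277 CPM and IL6 from 28.05 ± 0.622 to 644 ± 126 CPM. NF-kappaB pathway genes rose in 15 and fell in 1 of 19 cases. BIRC3, an inhibitor of apoptosis, rose 11.03-fold and the feedback inhibitor TNFAIP3 9.33-fold. The NF-kappaB list had a median log2 change of 0.62 (camera adjusted p = 9.07e-05, and adjusted p = 0.279 with an estimated correlation). Among 25 p53 targets 21 rose and 2 fell. The antiproliferative BTG2 rose 10.8-fold and the stress cytokine GDF15 10.1-fold. The p53 list had a median log2 change of 0.83 (camera adjusted p = 2.53e-06, and adjusted p = 0.119 with an estimated correlation).

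Lysosomal genes rose in 24 or, adjusted over the list alone, 25 and fell in 1 or, adjusted over the list alone, 2 of 31 cases. The fucosidase FUCA1 rose from 0.186 ± 0.0209 to 4.11 ± 0.133 CPM. The cathepsins CTSS and CTSK rose by log2 2.60 and 1.29. The lysosomal list had a median log2 change of 0.62 (camera adjusted p = 1.12e-06, and adjusted p = 0.186 with an estimated correlation). Collagens and matrix proteins rose in 27 and fell in 4 of 36 cases. The collagen cross-linking enzyme LOX rose 4.87-fold and COL8A1 4.77-fold. The collagen list had a median log2 change of 0.89 (camera adjusted p = 5.55e-05, and adjusted p = 0.575 with an estimated correlation). Of 15 MHC class I presentation genes 11 rose and 1 fell. HLA-B rose from 77.4 ± 12.8 to 708 ± 10.2 CPM and its light chain B2M from 107 ± 1.29 to 329 ± 10.6 CPM. The MHC list had a median log2 change of 0.74 (camera adjusted p = 0.00142, and adjusted p = 0.186 with an estimated correlation). Counts in the MHC region (chromosome 6, 29723434 to 33314078) were low. In all, 107 of its 137 coding genes stayed under 1 CPM in all libraries (78.1%), against 37.9% of other coding genes. Levels of the HLA genes and of other genes in the region, such as MICA, carry that limit.

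Ligands of NK and T cell receptors rose in 9 and fell in 2 of 15 cases, and the checkpoint ligand CD274 rose from 24.3 ± 1.599 to 76.2 ± 2.13 CPM. Without senescent replicate 1 lacking doxycycline this list call was lost (camera adjusted p = 0.0544). The NK ligand list had a median log2 change of 0.66 (camera adjusted p = 0.0372, and adjusted p = 0.1905 with an estimated correlation). Mitochondrially encoded mRNAs rose in 8 or, adjusted over the list alone, 9 of 13 cases. Their call was lost without proliferating replicate 1 (adjusted p = 0.0720), without senescent replicate 1 (0.0818) and with total counts only (0.0666). The mitochondrial list had a median log2 change of 0.55 (camera adjusted p = 0.0372, and adjusted p = 0.607 with an estimated correlation). Neither the YAP/TAZ-TEAD targets (camera adjusted p = 0.0701), the Hippo genes (0.368), the TGF-beta genes (0.05502), the smooth-muscle genes (0.0545) nor the unfolded protein response genes (0.0545) passed as lists. The same held for the AP-1 genes (0.184), the BCL2 family (0.184), the ATF4 targets (0.424), the focal adhesion genes (0.4298) and the cholesterol genes (0.943, with a median of 0.06, -0.12 with total counts only, and a mean of -0.12). Single members of these lists changed strongly. ANKRD1, a widely used YAP target, rose from 3.38 ± 0.429 to 83.1 ± 16.2 CPM. IGFBP3 rose 20.6-fold, and the BMP target ID1 fell from 48.5 ± 4.84 to 7.26 ± 1.85 CPM. The markers of other cell types did not pass either, with camera adjusted p = 0.994 for epithelial, 0.2398 for endothelial, 0.943 for leukocyte and 0.956 for neuronal and glial genes. The epithelial and neuronal medians were 0.11 (-0.07 with total counts only) and 0.38 and the means 1.69 and 0.11, while camera's direction was down for both.

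Doxycycline in proliferating cells asks what the induced transgene does without DNA damage. ANKRD1 (chromosome 10, 90912096 to 90921087) rose from 3.38 ± 0.429 to 272 ± 7.95 CPM (80.3-fold, log2 SE 0.15). TGFB2, a TGF-beta ligand, rose from 7.35 ± 0.695 to 138 ± 20.7 CPM. LATS2, the kinase that phosphorylates and restrains YAP (chromosome 13, 20973036 to 21061586), rose from 57.6 ± 0.572 to 164 ± 13.9 CPM (2.85-fold, log2 SE 0.08). Several genes with no counts in untreated proliferating cells appeared. The natriuretic peptide gene NPPB reached 23.02 ± 5.68 CPM (at least 610.3-fold higher), the microfibril gene MFAP5 13.04 ± 0.469 CPM (at least 352-fold) and CXCR4 3.51 ± 0.325 CPM (at least 93.95-fold). In the other direction, VCAM1, an adhesion receptor for leukocytes (chromosome 1, 100719742 to 100739045), fell from 10.4 ± 1.36 to 0.704 ± 0.412 CPM (14.2-fold lower, log2 SE 0.35). IL6 (chromosome 7, 22727200 to 22731998) fell from 28.05 ± 0.622 to 6.17 ± 0.631 CPM (4.56-fold lower, log2 SE 0.26).

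By the same edgeR test 3938 of 17155 genes changed, 2158 higher and 1780 lower. Of these 675 and 209 changed more than 2-fold in the fit. The count rested in part on the untreated proliferating libraries and was lower without either of them. These replicates were the closest pair, with chi-square per degree of freedom of 3.63 against 12.7 to 19.5 in the other groups. The model pools the spread of a gene over the groups, so this pair enters the p-values of every contrast. Among the largest rises were also SERPINA9 (log2 7.55), the gap junction gene GJA5 (6.84), the chemerin receptor gene CMKLR2 (6.62) and OR7E19P (at least 158-fold). The last is an olfactory receptor pseudogene whose reads are uncertain because close paralogs exist. The largest falls included the cytokine gene CSF2 (log2 -2.64), the complement genes C3 (-2.31) and MASP1 (-2.12), NPTX1 (-2.07) and the hyaluronidase gene CEMIP (-2.07). MX2, at 0.262 ± 0.232 CPM before and 3 counts over both libraries after (ratio 6.51, 95% counting interval 1.94 to 34.1), lost its call without untreated replicate 2 (adjusted p = 0.511), treated replicate 1 (0.0573) or treated replicate 2 (0.135). It was also lost with limma-voom (0.108) and with only the 4 libraries compared (0.107).

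YAP/TAZ-TEAD targets rose in 12 and fell in 2 of 22 cases, and CCN2 did not pass. AMOTL2, which binds YAP, rose from 146 ± 2.03 to 291 ± 29.8 CPM. The TEAD target list had a median log2 change of 0.29 (camera adjusted p = 0.000481, and adjusted p = 0.2801 with an estimated correlation). Hippo pathway genes and TEAD factors went both ways, 7 or, adjusted over the list alone, 8 higher and 7 lower of 27 (camera adjusted p = 0.686, adjusted p = 0.856 with an estimated correlation). The scaffold WWC1 rose 7.74-fold, NF2 1.47-fold and AJUBA 1.53-fold. The protocadherin DCHS1 fell from 84.4 ± 4.39 to 45.6 ± 6.55 CPM.

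Cell cycle genes were lower by a modest amount. Mitotic genes fell in 26 or, adjusted over the list alone, 28 of 30 cases and rose in none. DNA replication genes fell in 25 or, adjusted over the list alone, 28 of 30 and rose in none. The mitotic list had a median log2 change of -0.43 (camera adjusted p = 9.26e-09, and adjusted p = 0.2801 with an estimated correlation). The replication list had a median log2 change of -0.43 (camera adjusted p = 6.84e-09, and adjusted p = 0.2801 with an estimated correlation). TOP2A, the topoisomerase of dividing cells, went from 377 ± 16.1 to 235 ± 8.41 CPM and the helicase subunit MCM6 from 117 ± 1.22 to 75.3 ± 4.44 CPM. Senescence regulators and chromatin genes fell in 10 or, adjusted over the list alone, 15 and rose in 1 of 23 cases. The senescence regulator list had a median log2 change of -0.29 (camera adjusted p = 0.000481, and adjusted p = 0.263 with an estimated correlation). LMNB1 fell to 77.2 ± 0.971 CPM. CDKN2A, which encodes the p16 inhibitor and ARF (chromosome 9, 21967752 to 21995324), rose from 11.6 ± 0.00398 to 42.5 ± 6.36 CPM. Among p53 targets 12 rose and 1 fell of 25. BTG2 rose 2.13-fold and the metabolic phosphatase TIGAR 1.59-fold. CDKN1A, at 324 ± 1.04 and 378 ± 40.6 CPM, did not pass. The p53 list had a median log2 change of 0.25 (camera adjusted p = 0.00795, and adjusted p = 0.263 with an estimated correlation).

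Interferon-stimulated genes, already low in dividing cells, fell in 16 or, adjusted over the list alone, 17 and rose in 1 of 34 cases. OAS2 fell from 0.755 ± 0.0664 to 0.192 ± 0.106 CPM and IFIT1, with uncertain reads because it lies within the span of LIPA, rose from 16.8 ± 0.905 to 40.6 ± 2.18 CPM. The interferon list had a median log2 change of -0.61 (camera adjusted p = 1.35e-05, and adjusted p = 0.2801 with an estimated correlation). NF-kappaB pathway genes fell in 10 and rose in 2 of 19 cases. The mitochondrial superoxide dismutase SOD2 went from 283 ± 3.996 to 183 ± 6.37 CPM. MHC class I genes fell in 4 or, adjusted over the list alone, 5 of 15. The NF-kappaB list had a median log2 change of -0.26 (camera adjusted p = 0.008502, and adjusted p = 0.483 with an estimated correlation). The MHC list had a median log2 change of -0.21 (camera adjusted p = 0.00795, and adjusted p = 0.2801 with an estimated correlation). The libraries of both groups overlapped in the mean log2 CPM of this list. Relative to the untreated mean it was -0.200 and 0.200 without doxycycline and -0.115 and -0.345 with it. Secreted factors moved in both directions, 6 higher and 9 lower of 29 (camera adjusted p = 0.113, adjusted p = 0.647 with an estimated correlation). The protease inhibitor SERPINB2 rose 7.09-fold and CSF2 fell 6.24-fold.

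Collagens and matrix proteins fell in 21 and rose in 7 or, adjusted over the list alone, 8 of 36 cases. COL8A1 rose 6.24-fold and the fibrillin FBN2 4.61-fold. The collagen list had a median log2 change of -0.56 (camera adjusted p = 0.00284, and adjusted p = 0.582 with an estimated correlation). Fry did not call it (adjusted p = 0.105). Smooth-muscle genes fell in 6 or, adjusted over the list alone, 7 and rose in 1 of 16 cases. MYOCD, the coactivator of smooth-muscle genes, fell from 32.4 ± 0.295 to 8.42 ± 0.833 CPM. The smooth-muscle list had a median log2 change of -0.15 (camera adjusted p = 0.0499, and adjusted p = 0.524 with an estimated correlation). That list call was lost without doxycycline-treated proliferating replicate 2 (adjusted p = 0.0937), without either senescent library with doxycycline (0.0607 and 0.0603) and without either senescent library lacking it (0.0664 and 0.0665). It was also lost with the title's replicate number as a block (0.0531). Focal adhesion and actin genes fell in 11 or, adjusted over the list alone, 12 and rose in 3 of 31 cases. Their call was lost without replicate 1 of either proliferating group (0.0547 untreated, 0.213 with doxycycline) and without either senescent library lacking doxycycline (0.0555 and 0.0555). The focal adhesion list had a median log2 change of -0.12 (camera adjusted p = 0.0423, and adjusted p = 0.647 with an estimated correlation). Fry did not call it (adjusted p = 0.100). ITGA1, a collagen receptor subunit, fell from 267 ± 5.09 to 128 ± 11.98 CPM and the filamin FLNC rose from 734 ± 16.7 to 1405 ± 214 CPM.

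Ribosome biogenesis genes rose in 16 or, adjusted over the list alone, 19 of 26 cases and fell in none. RRP12, a factor of ribosome maturation, rose from 32.4 ± 0.3997 to 54.1 ± 2.93 CPM. The ribosome biogenesis list had a median log2 change of 0.32 (camera adjusted p = 2.34e-06, and adjusted p = 0.263 with an estimated correlation). Cholesterol synthesis genes rose in 8 or, adjusted over the list alone, 9 and fell in 1 of 24 cases. DHCR7, the last enzyme of the pathway, rose 2.44-fold. The list call was lost without doxycycline-treated replicate 1 (0.0835) and without untreated replicate 2 (0.0596). The cholesterol list had a median log2 change of 0.17 (camera adjusted p = 0.0263, and adjusted p = 0.2801 with an estimated correlation). ATF4 targets and amino acid genes fell in 13 or, adjusted over the list alone, 14 and rose in 3 or, adjusted over the list alone, 5 of 28 cases. The ATF4 list had a median log2 change of -0.20 (camera adjusted p = 0.00989, and adjusted p = 0.381 with an estimated correlation). DDIT4, an inhibitor of mTORC1, fell from 62.5 ± 0.386 to 18.4 ± 2.89 CPM. Both subunits of a leucine transporter rose, SLC7A5 from 187 ± 1.18 to 597 ± 54.8 and SLC3A2 from 116 ± 2.65 to 228 ± 11.8 CPM. Mitochondrially encoded mRNAs rose in 5 of 13 cases and fell in none. The mitochondrial list had a median log2 change of 0.25 (camera adjusted p = 0.001797, and adjusted p = 0.505 with an estimated correlation). Epithelial markers rose in 4 of 7 cases. The keratin genes KRT18 and KRT8 rose from 159.8 ± 3.29 to 392 ± 3.55 and from 47.2 ± 2.92 to 90.2 ± 2.07 CPM, while CDH1 reached only 0.307 ± 0.184 CPM and KRT14 0.266 ± 0.00155 CPM. The epithelial list had a median log2 change of 0.93 (camera adjusted p = 0.0193, and adjusted p = 0.2801 with an estimated correlation).

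**Figure D1:**
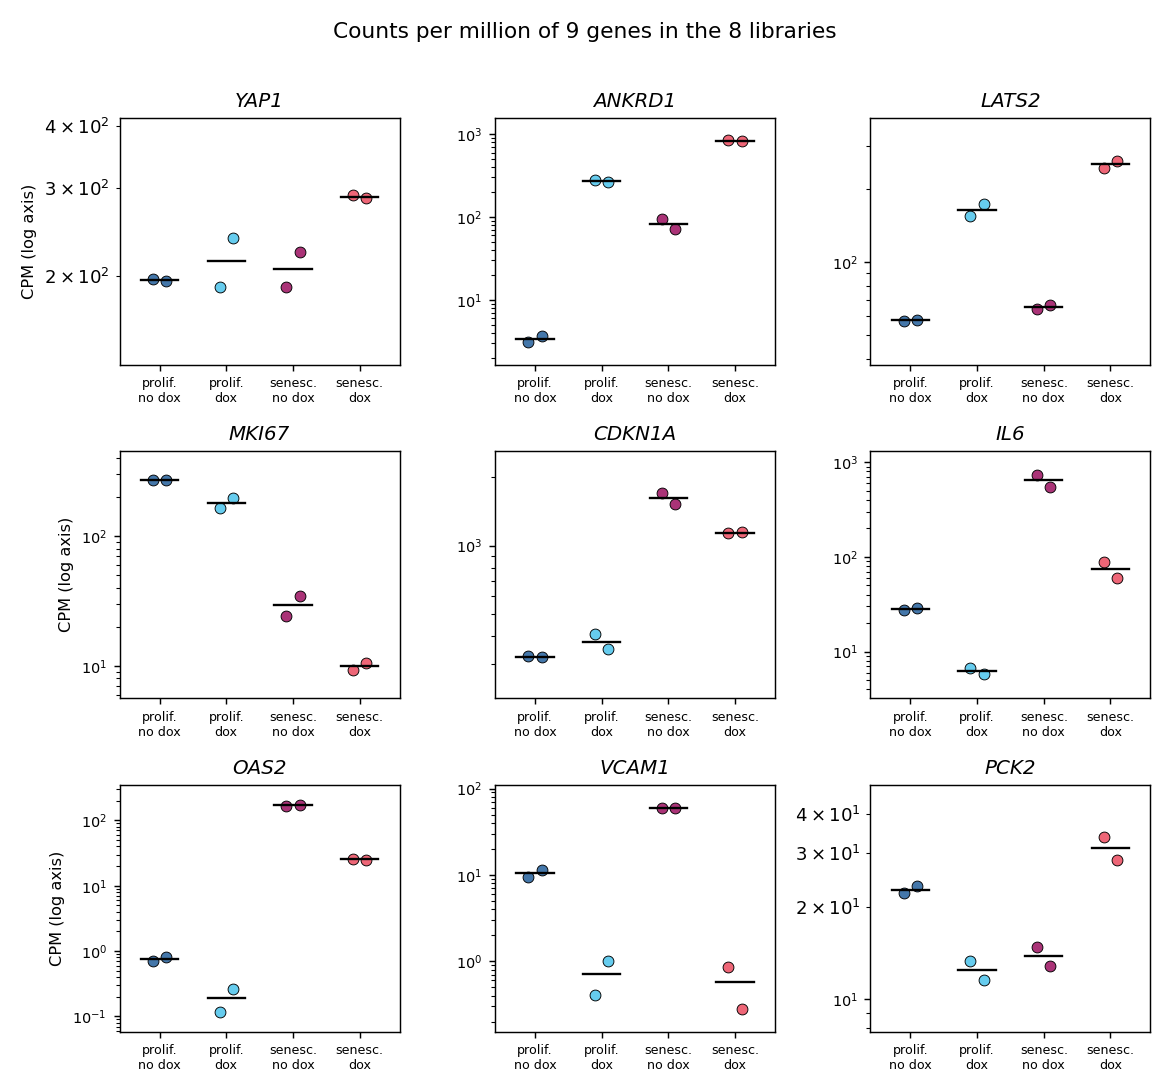
Level of 9 genes in the 8 libraries, in CPM on a log axis, with a point for each library and a line at each group's mean. ANKRD1 and LATS2 sit higher with doxycycline in both states, and IL6, OAS2 and VCAM1 are high in senescent cells without doxycycline and lower with it.

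Doxycycline in senescent cells asks how cells that had the induced transgene during DNA damage and after it differ from damaged cells without it. Interferon-stimulated and inflammatory genes fell together. OAS2 fell from 169.7 ± 4.61 to 25.6 ± 0.662 CPM and BST2 (chromosome 19, 17402939 to 17405630) from 283 ± 56.6 to 25.6 ± 3.63 CPM (11.02-fold lower, log2 SE 0.16). IL6 fell from 644 ± 126 to 74.5 ± 20.6 CPM (8.63-fold lower, log2 SE 0.23). VCAM1 fell from 60.02 ± 0.309 to 0.573 ± 0.414 CPM (102-fold lower, log2 SE 0.34). Among YAP targets, which as a list moved both ways, ANKRD1 rose from 83.1 ± 16.2 to 837 ± 20.7 CPM (10.1-fold). LATS2 rose from 65.3 ± 1.61 to 252 ± 10.9 CPM (3.85-fold). MKI67, the proliferation marker (chromosome 10, 128096659 to 128126423), fell from 29.3 ± 7.33 to 9.92 ± 0.846 CPM.

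By edgeR's test 7951 of 17155 genes changed, 3874 higher and 4077 lower. Of these 1367 and 953 changed more than 2-fold in the fit. With total counts as the only scaling the median of all genes moved by 0.17 on the log2 scale, and 69.3% of the called genes were higher, against 48.7% with the TMM factors. Large rises were those of MFAP5 (3 counts over the group without doxycycline, ratio 1952, 95% counting interval 668 to 9469) and NPPB (log2 9.42). Others were CXCR4 (log2 6.05), the kinase gene CDK18 (6.04), GJA5 (5.91), the small heat shock protein gene CRYAB (5.61) and PTPRQ (4.88). The pseudogene OR7E19P, whose reads are uncertain and which had 1 count in that group, gave a ratio of 2638, 95% counting interval 473 to 104234. Large falls besides those above were MX2 (log2 -3.19), IFI44L (-3.16), EHF (-3.13), C3 (-3.13) and the chemokine gene CXCL10 (-3.10).

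Interferon-stimulated genes fell in 33 of 34 cases and rose in none. The interferon list had a median log2 change of -1.70 (camera adjusted p = 5.12e-15, and adjusted p = 0.284 with an estimated correlation). Senescence-associated secreted factors fell in 23 and rose in 2 of 29. CXCL8 went from 1027 ± 277 to 280.2 ± 57.1 CPM, IL1A from 109 ± 34.3 to 18.6 ± 3.05 CPM and GDF15 from 79.7 ± 17.8 to 28.8 ± 3.37 CPM. The secreted-factor list had a median log2 change of -1.36 (camera adjusted p = 3.24e-07, and adjusted p = 0.284 with an estimated correlation). NF-kappaB pathway genes fell in 14 or, adjusted over the list alone, 15 of 19 cases and rose in none. The kinase gene IRAK2 fell from 40.1 ± 0.291 to 12.5 ± 1.88 CPM and NFKBIA from 125 ± 18.4 to 55.6 ± 1.67 CPM. The NF-kappaB list had a median log2 change of -0.70 (camera adjusted p = 1.34e-06, and adjusted p = 0.284 with an estimated correlation). MHC class I genes fell in 12 of 15 cases and rose in none. The peptide trimming enzyme ERAP2, with uncertain reads because it lies within the span of ERAP1, fell 3.85-fold and B2M 2.05-fold. The MHC list had a median log2 change of -0.75 (camera adjusted p = 5.21e-05, and adjusted p = 0.284 with an estimated correlation).

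Mitotic genes fell in 25 or, adjusted over the list alone, 26 of 30 cases and rose in none. KIF20A, a kinesin of cytokinesis, fell from 6.298 ± 0.954 to 2.81 ± 0.2099 CPM. The mitotic list had a median log2 change of -0.76 (camera adjusted p = 1.19e-08, and adjusted p = 0.284 with an estimated correlation). DNA replication genes fell in 14 and rose in 2 of 30 cases. RRM2, which makes deoxynucleotides, went from 65.4 ± 12.4 to 24.9 ± 2.41 CPM. The replication list had a median log2 change of -0.32 (camera adjusted p = 0.00172, and adjusted p = 0.556 with an estimated correlation). Among p53 targets 9 fell and 2 rose of 25. With total counts only the median changed sign to 0.02 and the list call was lost (camera adjusted p = 0.137), while camera's direction did not reverse. GDF15 fell 2.77-fold and BTG2 1.65-fold. The list call was also lost without doxycycline-treated senescent replicate 1 (0.0739). The p53 list had a median log2 change of -0.15 (camera adjusted p = 0.0337, and adjusted p = 0.284 with an estimated correlation). CDKN2A rose from 29.2 ± 4.57 to 52.7 ± 3.06 CPM and its neighbour CDKN2B (chromosome 9, 22002903 to 22009313) fell from 19.2 ± 1.36 to 9.48 ± 0.239 CPM.

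Matrix and contractile genes were mostly lower. Collagens and matrix proteins fell in 25 or, adjusted over the list alone, 26 and rose in 6 of 36 cases. Tenascin TNC fell from 677 ± 56.9 to 86.4 ± 7.84 CPM and POSTN from 5.01 ± 0.827 to 0.495 ± 0.0517 CPM. COL11A1 rose from 0.394 ± 0.00223 to 10.2 ± 2.998 CPM. The collagen list had a median log2 change of -0.91 (camera adjusted p = 3.30e-05, and adjusted p = 0.496 with an estimated correlation). Smooth-muscle genes fell in 9 and rose in 1 of 16 cases. The smooth-muscle list had a median log2 change of -0.65 (camera adjusted p = 0.00172, and adjusted p = 0.358 with an estimated correlation). ACTA2, the actin of myofibroblasts (chromosome 10, 88935074 to 88991337), fell from 616 ± 1.75 to 155 ± 18.7 CPM, and SYNPO2 rose from 11.2 ± 3.76 to 132 ± 9.36 CPM. Focal adhesion genes fell in 16 and rose in 8 of 31 cases. Their call was lost without doxycycline-treated senescent replicate 1 (0.112). The focal adhesion list had a median log2 change of -0.33 (camera adjusted p = 0.0337, and adjusted p = 0.665 with an estimated correlation). YAP/TAZ-TEAD targets rose in 12 and fell in 5 of 22 cases. Their call was lost without doxycycline-treated senescent replicate 2 (0.0576). The TEAD target list had a median log2 change of 0.26 (camera adjusted p = 0.0199, and adjusted p = 0.496 with an estimated correlation).

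Lysosomal genes fell in 18 or, adjusted over the list alone, 19 and rose in 2 of 31 cases, and CTSK fell from 53.1 ± 2.61 to 12.04 ± 0.936 CPM. The lysosomal list had a median log2 change of -0.34 (camera adjusted p = 0.000109, and adjusted p = 0.284 with an estimated correlation). All 13 mitochondrially encoded mRNAs fell. The mitochondrial list had a median log2 change of -0.9999 (camera adjusted p = 5.38e-07, and adjusted p = 0.284 with an estimated correlation). COX1, a subunit of cytochrome oxidase, went from 12591 ± 228 to 5539 ± 268 CPM and ND5, a subunit of complex I, from 6378 ± 554 to 2568 ± 214 CPM. ATF4 targets and amino acid genes rose in 19 or, adjusted over the list alone, 21 and fell in 4 or, adjusted over the list alone, 5 of 28 cases. SLC7A5 rose from 222 ± 15.8 to 1685 ± 27.1 CPM and PSAT1, an enzyme of serine synthesis, from 41.1 ± 0.645 to 119 ± 9.08 CPM. The ATF4 list had a median log2 change of 0.40 (camera adjusted p = 0.000169, and adjusted p = 0.284 with an estimated correlation). Unfolded protein response genes fell in 10 and rose in 2 of 17 cases. Their call was lost without doxycycline-treated senescent replicate 1 (0.0508). The unfolded protein list had a median log2 change of -0.43 (camera adjusted p = 0.0198, and adjusted p = 0.556 with an estimated correlation). Epithelial markers rose in 4 of 7 cases, and KRT18 rose from 85.3 ± 2.101 to 479.6 ± 24.4 CPM. With total counts only the list call was lost (adjusted p = 0.0569). The epithelial list had a median log2 change of 1.74 (camera adjusted p = 0.0178, and adjusted p = 0.284 with an estimated correlation). The other 11 lists did not pass, including ribosome biogenesis genes (camera adjusted p = 0.506), AP-1 genes (0.6005) and TGF-beta genes (0.316, with a median of -0.24). The phosphatase gene DUSP5 of the AP-1 list rose 5.25-fold.

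Bleomycin with doxycycline asks which part of the senescent programme was present while the transgene was induced. The fall of mitotic genes was also present. PLK1 fell from 106 ± 1.07 to 3.05 ± 0.277 CPM (34.7-fold lower, log2 SE 0.11), and BIRC5, also called survivin, from 117 ± 11.3 to 4.34 ± 0.7403 CPM. Interferon-stimulated genes rose as well. OAS2 rose from 0.192 ± 0.106 to 25.6 ± 0.662 CPM (126-fold, log2 SE 0.18). CDKN1A rose 3.02-fold to 1142 ± 5.196 CPM. The chemokine gene CXCL8 (chromosome 4, 73740569 to 73743716) went from 5.40 ± 0.396 to 280.2 ± 57.1 CPM and CSF2 from 0.0997 ± 0.0993 to 14.4 ± 1.38 CPM.

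The edgeR test called 9519 of 17155 genes here, 4600 higher and 4919 lower. Of these 1912 and 1357 changed more than 2-fold in the fit. Other large rises were OAS1 (log2 8.15), BST2 (6.89), IL1A (5.69), C3 (5.63) and MX2 (3 counts over the proliferating group, ratio 238, 95% counting interval 81.1 to 1156). Other large falls were TROAP (log2 -5.17), CDC20 (-4.87), KIF20A (-4.84), DLGAP5 (-4.64), PIMREG (-4.60) and the cytidine deaminase gene APOBEC3B (-4.59). All 30 mitotic genes and all 30 replication genes fell. The mitotic list had a median log2 change of -3.51 (camera adjusted p = 5.12e-20, and adjusted p = 0.175 with an estimated correlation). The replication list had a median log2 change of -2.48 (camera adjusted p = 1.34e-17, and adjusted p = 0.185 with an estimated correlation). Interferon-stimulated genes rose in 33 of 34 cases and secreted factors in 26 of 29 with 1 lower. NF-kappaB genes rose in 13 of 19 with 4 lower and p53 targets in 16 of 25 with 3 or, adjusted over the list alone, 5 lower. The interferon list had a median log2 change of 2.88 (camera adjusted p = 6.49e-17, and adjusted p = 0.149 with an estimated correlation). The secreted-factor list had a median log2 change of 1.83 (camera adjusted p = 3.06e-09, and adjusted p = 0.185 with an estimated correlation). The NF-kappaB list had a median log2 change of 0.44 (camera adjusted p = 0.0135, and adjusted p = 0.516 with an estimated correlation). The p53 list had a median log2 change of 0.49 (camera adjusted p = 0.00109, and adjusted p = 0.149 with an estimated correlation). Senescence regulators and chromatin genes fell in 16 and rose in 5 of 23 cases. The senescence regulator list had a median log2 change of -1.51 (camera adjusted p = 0.000257, and adjusted p = 0.149 with an estimated correlation).

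Ribosome biogenesis genes fell in 21 or, adjusted over the list alone, 22 of 26 cases and rose in none. Mitochondrially encoded mRNAs fell in 12 of 13 and rose in none, and COX3 fell from 7887 ± 411 to 2651 ± 319 CPM. The ribosome biogenesis list had a median log2 change of -0.69 (camera adjusted p = 5.47e-06, and adjusted p = 0.156 with an estimated correlation). The mitochondrial list had a median log2 change of -0.92 (camera adjusted p = 5.56e-05, and adjusted p = 0.402 with an estimated correlation). ATF4 targets rose in 20 and fell in 4 of 28 cases. The lipoprotein receptor VLDLR rose from 1.91 ± 0.00358 to 25.7 ± 4.42 CPM. Epithelial markers rose in 5 of 7. The ATF4 list had a median log2 change of 0.58 (camera adjusted p = 0.000118, and adjusted p = 0.211 with an estimated correlation). The epithelial list had a median log2 change of 0.54 (camera adjusted p = 0.0255, and adjusted p = 0.211 with an estimated correlation). YAP/TAZ-TEAD targets rose in 11 and fell in 4 of 22 cases, and CCN2 rose from 823 ± 28.4 to 1789 ± 16.8 CPM. The list call was lost without doxycycline-treated proliferating replicate 1 (0.111) and senescent replicate 2 (0.0937). The TEAD target list had a median log2 change of 0.24 (camera adjusted p = 0.0323, and adjusted p = 0.5301 with an estimated correlation). Collagens rose in 21 and fell in 10 of 36 and TGF-beta genes rose in 11 and fell in 6 of 22. The collagen list had a median log2 change of 0.45 (camera adjusted p = 0.0414, and adjusted p = 0.6901 with an estimated correlation). The TGF-beta list had a median log2 change of 0.63 (camera adjusted p = 0.04596, and adjusted p = 0.628 with an estimated correlation). Without doxycycline-treated proliferating replicate 1 both calls were lost (0.141 and 0.0885), likewise without doxycycline-treated senescent replicate 2 (0.154 and 0.106). They were also lost without each untreated proliferating library (0.0505 and 0.0522 for either) and without each untreated senescent library (0.0517 and 0.0897 for either). With the title's replicate number as a block both were lost as well (0.0512 and 0.0568). MHC class I genes, which rose in 6 and fell in 3 of 15 cases, did not pass as a list (camera adjusted p = 0.453, adjusted p = 0.6901 with an estimated correlation). Nor did lysosomal genes, with 12 higher and 8 or, adjusted over the list alone, 9 lower of 31 (camera adjusted p = 0.251, adjusted p = 0.6901 with an estimated correlation). The smooth-muscle list had a median of -0.05, a mean of 0.30 and camera adjusted p = 0.924.

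**Figure D2:**
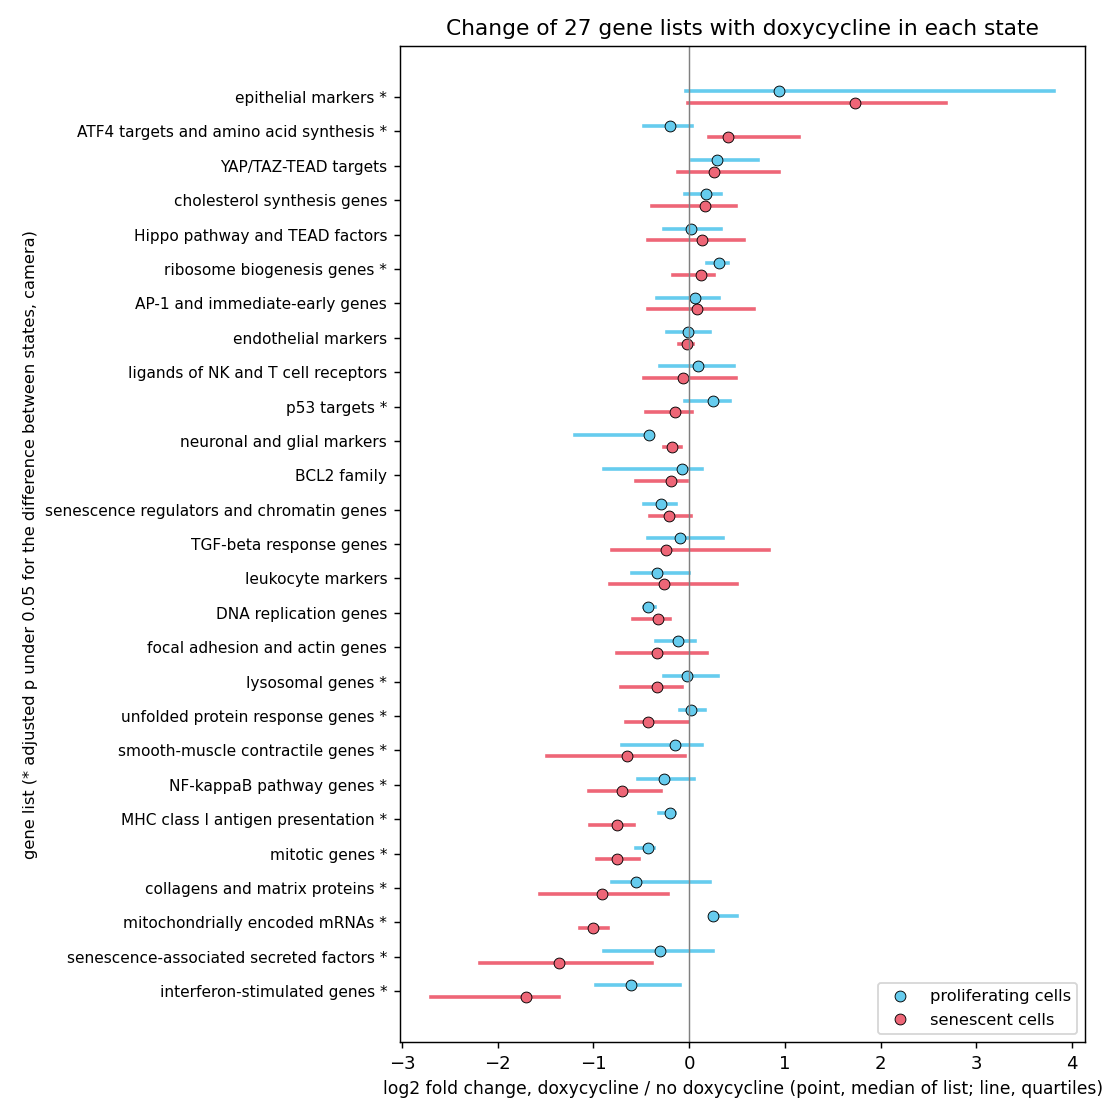
Median (point) and quartiles (line) of the log2 fold change with doxycycline for 27 gene lists, in proliferating and in senescent cells. A star marks a list with camera adjusted p under 0.05 for the difference between the states, and the interferon list sits at -0.61 and -1.70 and the ATF4 list at -0.20 and 0.40.

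Whether the doxycycline effect differed between the states was tested by the interaction of the 2 factors. The ATF4 targets differed by camera's test (adjusted p = 1.42e-08), though not with an estimated correlation (adjusted p = 0.215). DDIT4 (chromosome 10, 72273924 to 72276036) fell from 62.5 ± 0.386 to 18.4 ± 2.89 CPM in proliferating cells and did not pass in senescent cells, at 53.98 ± 7.297 and 64.6 ± 9.48 CPM (interaction log2 2.03, SE 0.18). PCK2, the mitochondrial PEP carboxykinase (chromosome 14, 24094171 to 24104125), fell from 22.7 ± 0.855 to 12.4 ± 1.23 CPM and rose from 13.8 ± 1.37 to 31.05 ± 3.88 CPM (interaction log2 2.05, SE 0.16). IFIT1, an antiviral RNA-binding protein (chromosome 10, 89392623 to 89406487), rose with doxycycline in proliferating cells and fell in senescent cells from 381 ± 0.622 to 144 ± 7.21 CPM (interaction log2 -2.67, SE 0.12). The collagenase gene MMP1 rose from 289 ± 9.17 to 518 ± 29.6 CPM and fell from 2321 ± 454 to 709 ± 78.1 CPM (interaction log2 -2.56). IFIT1 lies within the span of LIPA and MMP1 within that of the pseudogene WTAPP1, so the reads of both are uncertain. ANKRD1 rose in both states and less steeply in senescent cells, where its level without doxycycline was already higher (interaction log2 -2.9968, SE 0.18).

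For the interaction the edgeR test called 3407 of 17155 genes, 1386 with a higher and 2021 with a lower change in senescent cells. Of these 417 and 520 differed more than 2-fold in the fit. Without untreated proliferating replicate 1 the count was 1928, without replicate 2 of that group 1851 and without doxycycline-treated senescent replicate 1 it was 2012. With total counts as the only scaling the median of all genes moved by 0.18 on the log2 scale and 70.5% of the called genes were higher, against 40.7% with the TMM factors. Of the 3407 genes, 675 were called in the same direction in both states, 213 in opposite directions, 2008 in senescent cells alone, 396 in proliferating cells alone and 115 in neither. Among genes with a mean log2 CPM of at least 3, the largest positive differences were those of the translation factor gene EEF1A2 (log2 3.35), SYNPO2 (3.12), the actin pseudogene ACTG1P20 (2.71), whose reads are uncertain, the hypoxia-induced carbonic anhydrase CA9 (2.62), the noncoding MIR193BHG (2.32), PCK2 (2.05), DDIT4 (2.03) and VLDLR (2.01). Apart from CXCR4, whose untreated proliferating libraries had no counts, the largest negative ones were SERPINA9 (log2 -6.23), the BMP-binding BMPER (-4.36), the protease gene PAPPA (-4.28), the pseudogene WTAPP1 (-3.17), SERPINB2 (-3.10), ANKRD1 (-2.9968) and LCE2A (-2.91). WTAPP1 overlaps MMP1, so its reads are uncertain.

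Lists with a lower change in senescent cells were the interferon-stimulated genes (21 or, adjusted over the list alone, 24 lower and 0 higher of 34), the secreted factors (13 or, adjusted over the list alone, 14 lower and 1 higher of 29) and the NF-kappaB genes (10 or, adjusted over the list alone, 12 lower and 0 higher of 19). The interferon list had a median log2 change of -1.11 (camera adjusted p = 4.79e-13, and adjusted p = 0.215 with an estimated correlation). The secreted-factor list had a median log2 change of -0.93 (camera adjusted p = 2.31e-06, and adjusted p = 0.252 with an estimated correlation). The NF-kappaB list had a median log2 change of -0.38 (camera adjusted p = 0.000238, and adjusted p = 0.335 with an estimated correlation). The same held for p53 targets (13 or, adjusted over the list alone, 16 lower and 0 higher of 25), MHC class I genes (8 or, adjusted over the list alone, 10 lower of 15) and lysosomal genes (18 or, adjusted over the list alone, 24 lower and 0 or, adjusted over the list alone, 2 higher of 31). CTSK and CDKN1A differed by log2 -1.99 and -0.73. The p53 list had a median log2 change of -0.45 (camera adjusted p = 6.13e-06, and adjusted p = 0.156 with an estimated correlation). The MHC list had a median log2 change of -0.57 (camera adjusted p = 0.000571, and adjusted p = 0.241 with an estimated correlation). The lysosomal list had a median log2 change of -0.49 (camera adjusted p = 2.21e-08, and adjusted p = 0.241 with an estimated correlation). All 13 mitochondrially encoded mRNAs had a lower change in senescent cells, from log2 -1.43 for ND1 to -1.53 for ND3 among the 4 largest. The mitochondrial list had a median log2 change of -1.36 (camera adjusted p = 9.46e-11, and adjusted p = 0.252 with an estimated correlation). Collagens (17 or, adjusted over the list alone, 21 lower and 4 higher of 36), smooth-muscle genes (9 lower and 1 higher of 16), unfolded protein response genes (9 lower of 17) and ribosome biogenesis genes (9 or, adjusted over the list alone, 12 lower and 1 higher of 26) followed. TNC differed by log2 -2.20 and ACTA2 by -1.23. The collagen list had a median log2 change of -0.58 (camera adjusted p = 0.000442, and adjusted p = 0.549 with an estimated correlation). Fry did not call it (adjusted p = 0.0855). The smooth-muscle list had a median log2 change of -0.50 (camera adjusted p = 0.00804, and adjusted p = 0.398 with an estimated correlation). The unfolded protein list had a median log2 change of -0.41 (camera adjusted p = 0.00104, and adjusted p = 0.398 with an estimated correlation). The ribosome biogenesis list had a median log2 change of -0.27 (camera adjusted p = 0.00215, and adjusted p = 0.252 with an estimated correlation).

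Mitotic genes had a lower change in 10 or, adjusted over the list alone, 12 of 30 cases. Their call was lost without untreated senescent replicate 2 (adjusted p = 0.0953). BIRC5 and PLK1 differed by log2 -0.97 and -0.76. The mitotic list had a median log2 change of -0.29 (camera adjusted p = 0.003496, and adjusted p = 0.549 with an estimated correlation). Fry did not call it (adjusted p = 0.108). ATF4 targets had a higher change in 18 or, adjusted over the list alone, 20 and a lower one in 3 or, adjusted over the list alone, 4 of 28 cases. The ATF4 list had a median log2 change of 0.86 (camera adjusted p = 1.42e-08, and adjusted p = 0.215 with an estimated correlation). Epithelial markers had a higher change in 2 of 7 cases, and KRT18 differed by log2 1.20. The mean of this list was -0.31. Its call was lost with total counts only (0.140), without untreated proliferating replicate 1 (0.0562), without doxycycline-treated proliferating replicate 1 (0.139) and without untreated senescent replicate 2 (0.0953). The epithelial list had a median log2 change of 0.43 (camera adjusted p = 0.0333, and adjusted p = 0.252 with an estimated correlation). The YAP/TAZ-TEAD targets did not pass (camera adjusted p = 0.5302, adjusted p = 0.832 with an estimated correlation), with TGFB2 at interaction log2 -2.54 and CCN2 at 1.03.

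**Figure D3:**
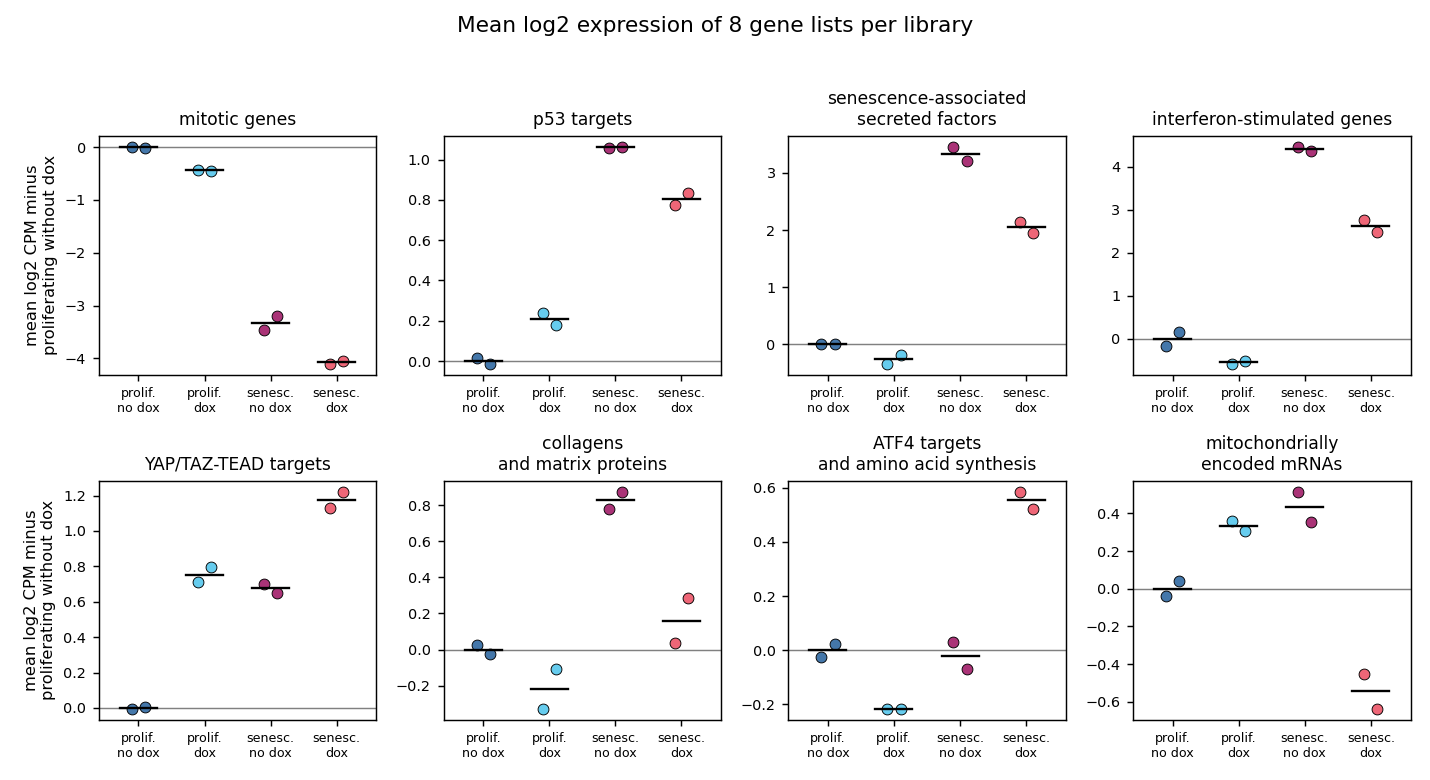
Mean log2 CPM of 8 gene lists in each library, relative to the mean of proliferating cells without doxycycline. The interferon list reaches 4.47 and 4.37 in senescent libraries without doxycycline and 2.77 and 2.48 with it, and the mitotic list -3.46 and -3.20 without and -4.10 and -4.04 with it.

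Across genes, the doxycycline effects in the states were related. Pearson r of the log2 changes was 0.556 over 17155 genes and 0.674 over the 9893 genes with a mean log2 CPM of at least 3. In 20 simulations of unchanged groups it had a mean of 0.00431. Both comparisons share no library, and genes are not independent replicates, so no p is given. Of the genes called in both states, 1391 rose in both (487 from the margins if independent) and 1191 fell in both (423). Another 125 rose in proliferating and fell in senescent cells (513) and 88 did the reverse (402). LATS2, AMOTL2 and NPPB were among those that rose in both, and VCAM1, IL6 and C3 among those that fell in both.

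A last comparison asks whether genes that differed with bleomycin differed in the opposite direction with doxycycline. As the drug was present throughout, a lower level with it can be a smaller rise and shows no order in time. Of the 5108 genes that bleomycin raised, 2030 were lower with doxycycline in senescent cells (1214 if independent) and 928 higher (1154). Of the 5047 that it lowered, 1568 were higher (1140) and 929 lower (1199). OAS2, BST2 and IL6 were among the genes higher with bleomycin and lower with doxycycline, and PLK1, BIRC5 and RRM2 among those lower with both. Both comparisons share the untreated senescent libraries with opposite sign, which alone gives a negative relation. Across genes r was -0.0948 with a covariance of -0.121, while simulated unchanged groups had a mean r of -0.514 and a mean covariance of -0.0517. The covariance was thus beyond the simulated one. For r the simulated value is no measure, since the changes of real genes enlarge the spread by which r is divided. With a different senescent library in each comparison, which removes the shared error, r was -0.0330 and -0.0477. The covariance was then -0.0482 and -0.0690, still negative but smaller in size than with the shared libraries. Without untreated senescent replicate 1 or replicate 2, r was -0.184 or -0.204.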

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

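All results in this part stood out because the effect of doxycycline differed between proliferating and senescent cells by the interaction test, which was planned; the tests of explanations were chosen after the results were seen, except those of GC content and gene length. There were 3407 such genes, among them 23 of those named for the largest rises and falls with doxycycline in either state or in the interaction. Genes named for the interaction were chosen among those past this test, so they are in that number by construction. C3, CMKLR2, CRYAB, EHF, IFI44L, MASP1 and VCAM1 were named for a state only. Of the lists 14 differed by camera at its preset correlation and 0 with an estimated one. Without untreated proliferating replicate 1, untreated proliferating replicate 2 or doxycycline-treated senescent replicate 1 the number of genes was 1928, 1851 or 2012.

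Genes that doxycycline raised in senescent cells and not in proliferating cells include EEF1A2, a translation factor of muscle and nerve, at 0.471 ± 0.149, 0.790 ± 0.119, 1.74 ± 0.476 and 30.1 ± 6.25 CPM (proliferating without and with, senescent without and with doxycycline; interaction log2 3.35), and SYNPO2, an actin-binding protein, at 2.04 ± 0.3296, 2.78 ± 0.265, 11.2 ± 3.76 and 132 ± 9.36 CPM (3.12). The noncoding MIR193BHG differed by 2.32 and the pseudogene ACTG1P20, with uncertain reads, by 2.71. The stress and metabolic genes CA9 (2.62), PCK2 (2.05), DDIT4 (2.03) and VLDLR (2.01) differed in the same direction, and so did the complement protease gene MASP1 (0.57), which fell in both states and less in senescent cells.

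Genes with a lower change in senescent cells include PAPPA, which cleaves IGF-binding proteins, at 5.96 ± 0.3197, 107 ± 19.2, 214 ± 24.8 and 199 ± 30.0 CPM (interaction log2 -4.28), and BMPER at 0.6301 ± 0.0408, 36.5 ± 1.31, 16.8 ± 1.86 and 47.2 ± 2.09 CPM (-4.36). SERPINA9 differed by -6.23, SERPINB2 by -3.10, ANKRD1 by -3.00, LCE2A by -2.91 and CMKLR2 by -2.25, all of them genes whose level in senescent cells without doxycycline was above that in proliferating cells without it. EHF, which did not pass in proliferating cells, differed by -2.85, and WTAPP1, with uncertain reads, by -3.17.

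For 5 genes the difference depended on single libraries, and for 4 of them on the method too. C3 (interaction log2 -0.82) had adjusted p from 0.0270 to 0.204 with each library left out and did not pass in 3 of 8 cases, highest without doxycycline-treated proliferating replicate 2. CRYAB (1.34) ranged from 0.00284 to 0.166 and missed in 5, highest without untreated proliferating replicate 1. VCAM1 (-2.84) ranged from 0.00140 to 0.0872 and missed in 5, highest without doxycycline-treated proliferating replicate 2, and IFI44L (-2.56) ranged from 0.00196 to 0.0539 and missed in 1, without the same library. CXCR4, with no counts in untreated proliferating cells, had an interaction adjusted p of 0.0395 and ranged from 0.0249 to 0.177, missing in 7, highest without untreated proliferating replicate 1. Under the 9 other alternatives, the 1.5-fold test aside, C3 missed in 3, CRYAB in 2 and CXCR4 in 4, each highest with limma-voom (0.0806, 0.106 and 0.153). VCAM1 missed in 2, highest with the description's number as a block (0.161), and IFI44L in 0.

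The 14 lists differed by these interaction medians (log2): interferon-stimulated genes -1.11, secreted factors -0.93, MHC class I genes -0.57, NF-kappaB genes -0.38, p53 targets -0.45, lysosomal genes -0.49, collagens -0.58, smooth-muscle genes -0.50, unfolded protein response genes -0.41, ribosome biogenesis genes -0.27, mitotic genes -0.29, mitochondrially encoded mRNAs -1.36, ATF4 targets 0.86 and epithelial markers 0.43. Without untreated senescent replicate 2 the calls of the mitotic and epithelial lists were lost (0.0953 each), and the epithelial call was also lost without replicate 1 of either proliferating group (0.0562 untreated, 0.139 with doxycycline) and with total counts only (0.140). No list passed with an estimated correlation, for which 5 had an unadjusted p under 0.05, and fry called 15. Fry did not call the collagens (adjusted p = 0.0855) and the mitotic genes (0.108) among the 14.

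Interferon-stimulated genes and secreted factors, OAS2, IL6 and CXCL10 among them, were lower with doxycycline in senescent cells. With total counts only the median of both lists together was -1.44 (quartiles -2.16 and -0.83). That scaling moves all genes by nearly the same amount, with a shift of 0.17 in the median of all genes. The choice between total counts and the TMM factors thus does not account for the fall. An error common to both scalings was not tested. GC content and gene length are argued against as the whole cause. The median was -1.63 after their correction and -1.61 before it, on the same 63 genes. Cells that kept dividing are argued against by the mitotic list, which was lower as well (median -0.76, quartiles -0.96 and -0.52). With 0 libraries given doxycycline without the transgene, an action of the drug itself cannot be told apart from one of YAP5SA, and repression of inflammatory genes by YAP5SA may be a hypothesis, which RNA levels in senescent cells given the drug without the transgene would check.

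Mitochondrially encoded mRNAs, such as COX1 and ND5, were lower with doxycycline in senescent cells and not in proliferating cells (median 0.25, quartiles 0.22 and 0.50). With total counts only the median in senescent cells was -0.83 (quartiles -0.97 and -0.68). The choice between total counts and the TMM factors thus does not account for the fall, and an error common to both was not tested. Doxycycline is known to inhibit mitochondrial translation, and a drug effect on senescent cells only cannot be told apart from one of the transgene, since 0 libraries had the drug alone.

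ATF4 targets, such as PCK2 and PSAT1, were higher with doxycycline in senescent cells and lower in proliferating cells. With total counts only the interaction median was 1.04 (quartiles 0.47 and 1.53). That scaling raised the interaction median of all genes by 0.18, the direction of the difference, so it could only enlarge it. It thus cannot decide whether scaling accounts for the difference, and an error common to both scalings was not tested. In the 27 of 28 genes with a value, the median was 0.88 both before and after correction for GC content and gene length. This argues against GC content and gene length as the whole cause. The drug acting differently on both states cannot be told apart from an effect of the transgene, with 0 libraries given the drug alone. No biological explanation was tested; a response to stress in mitochondria may be a hypothesis, which senescent cells given the drug without the transgene, with mitochondrial function measured, would check.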

How the results depend on the processing

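All alternatives in this part were planned, and none was chosen after a result was seen. No call of a named gene or list reversed by its test. With total counts only the median of the p53 targets with doxycycline in senescent cells changed sign, from -0.15 to 0.02, and so did medians of lists that were not called, the cholesterol (0.06 to -0.12) and epithelial (0.11 to -0.07) lists for bleomycin without doxycycline among them. Of the calls of named genes past the threshold, 606 held under every alternative and 437 were lost under at least 1, most often by the test against a 1.5-fold change (422 calls), which asks for more than a difference from 0. Total counts only ended 53 calls, the description's number as a block 70, DESeq2 30, limma-voom 29 and DESeq2's size factors in edgeR 8. A single library left out ended from 47 to 103, the most without untreated proliferating replicates 2 (103) and 1 (98) and doxycycline-treated senescent replicate 1 (80). Of the gene results not past the threshold 239 stayed so under every alternative and 88 passed under at least 1.

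The number of genes changed kept within 1.5 times its main value under both scalings, limma-voom, DESeq2, both filters, the fit without robust estimation and the 4 libraries alone. With the title's replicate number as a block the counts were 4355 for doxycycline in proliferating cells, 8281 in senescent cells, 10344 for bleomycin without doxycycline, 9746 with it and 3871 for the interaction. With the description's number as a block, doxycycline in proliferating cells changed 2353 genes. Description number 2 is that of untreated proliferating replicate 1 alone, so this block by construction takes that library out of the contrast, and without it the number was 2069. Against a 1.5-fold change the counts were 689, 2159, 4350, 3547 and 517 in the same order, by construction of that test.

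With each library left out, the counts ran from 2029 to 4166 for doxycycline in proliferating cells, from 5732 to 8566 in senescent cells, from 8247 to 10564 for bleomycin without doxycycline, from 7750 to 9689 with it and from 1851 to 3879 for the interaction. Doxycycline in proliferating cells changed 2069 genes without untreated proliferating replicate 1 and 2029 without replicate 2, and the interaction 1928 and 1851 without the same libraries and 2012 without doxycycline-treated senescent replicate 1. Each of these fits has 1 library fewer in a group of 2.

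Lists called by camera depended on the correlation between genes. With an estimated correlation 0 lists passed for doxycycline in proliferating cells, 0 in senescent cells, 0 for bleomycin without doxycycline, 0 with it and 0 for the interaction, where 3, 2, 5, 7 and 5 had an unadjusted p under 0.05. In simulated counts with a single changed list the estimated correlation called that list. Genes were drawn independently of each other there, so this does not show whether it would call a list of correlated genes. Fry called 22 lists for bleomycin without doxycycline against 13 by camera, as it asks another question. With each library left out the lists called were 14 to 16, 13 to 16, 11 to 16, 11 to 14 and 13 to 15 in that order of contrasts.

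The relation of both doxycycline effects across genes ranged from 0.492 to 0.543 with each library left out and was 0.674 over genes with a mean log2 CPM of at least 3. The relation of the doxycycline effect in senescent cells to the bleomycin effect ranged from -0.204 to -0.0749, reached -0.184 and -0.204 without untreated senescent replicates 1 and 2, and was -0.151 over genes with a mean log2 CPM of at least 3. With a different untreated senescent library in each contrast it was -0.0330 and -0.0477, which by construction removes the error they share.

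Depth limits the genes that were near 0 in a group. Library totals of 33627708 to 39692162 counts put the floor of 3 counts over a group at 0.0371 to 0.0437 CPM, so for NPPB, MFAP5 and CXCR4 the fold in proliferating cells is only a bound.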

Other observations

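The TEAD partners of YAP and their competitors were not all steady. TEAD2 was lower with doxycycline in both states, 33.8 ± 0.308 to 26.5 ± 0.301 CPM in proliferating and 20.3 ± 1.19 to 10.7 ± 0.352 CPM in senescent cells, and TEAD4 was higher in senescent cells with it (5.601 ± 0.871 to 11.4 ± 0.642 CPM). VGLL3, a cofactor that competes for TEAD binding, rose from 109 ± 11.4 to 271 ± 16.95 CPM there. BCL2L1, which encodes the survival factor BCL-XL on which many senescent cells rely, rose with doxycycline from 118 ± 0.927 to 176 ± 7.44 CPM in proliferating and from 163 ± 8.87 to 250.0 ± 0.412 CPM in senescent cells. The immediate-early gene EGR1 fell in both, from 98.8 ± 4.89 to 45.8 ± 4.19 CPM and from 39.1 ± 7.98 to 17.4 ± 0.315 CPM, and DUSP6, a phosphatase that restrains ERK, fell from 133 ± 13.9 to 56.4 ± 7.36 CPM in senescent cells.

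Single ligands read by lymphocytes moved with doxycycline, while their list did not pass (camera adjusted p = 0.339 in proliferating and 0.778 in senescent cells). ULBP2, a ligand of the NK receptor NKG2D, rose from 8.598 ± 0.561 to 23.5 ± 3.86 CPM in proliferating and from 20.6 ± 0.761 to 38.8 ± 0.101 CPM in senescent cells, and MICA from 11.2 ± 0.0383 to 20.6 ± 1.57 and from 17.7 ± 0.661 to 23.6 ± 1.47 CPM. MICA lies in the MHC region, so its levels carry the limit of the low counts there. CD276 fell in senescent cells from 143 ± 11.3 to 91.02 ± 6.03 CPM. In the endoplasmic reticulum, the chaperone HSPA5 fell from 1834 ± 57.9 to 1158 ± 93.7 CPM in senescent cells while the cochaperone DNAJB9 rose from 58.04 ± 2.55 to 95.3 ± 10.7 CPM. IGFBP3, a secreted IGF-binding protein, reached 12509 ± 1598 CPM in senescent cells and 9236 ± 1264 CPM with doxycycline.

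None of the markers of other cell types was tested for its origin. TEK, an endothelial receptor that fibroblasts can also express, was measured at 69.3 ± 1.17 CPM in proliferating and 144 ± 13.7 CPM in senescent cells, and TUBB3, a tubulin of neurons and of many dividing cells, at 89.9 ± 0.487 and 42.5 ± 2.902 CPM. Of the marker lists 7 epithelial, 5 endothelial, 4 leukocyte and 5 neuronal and glial genes were measured at all.

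Lists differed in how their summaries agreed on direction. With doxycycline in proliferating cells the lysosomal list had a median of -0.02, a mean of 0.07 and a test direction up, and the endothelial list -0.01, 0.21 and up. With bleomycin and doxycycline the smooth-muscle list had -0.05, 0.30 and down, and the leukocyte list 0.16, -0.02 and up. For bleomycin alone the cholesterol list had a median of 0.06 and a mean of -0.12. None of these passed by camera at its preset correlation.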
